A study of Mus musculus with 8 samples.

How the data were processed

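Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in cardiac progenitor cells made in culture from mouse embryonic stem cells. The labels name the line as GLI1-FTA and its strain as A2Lox.cre. They list 8 libraries in 3 groups: 2 control libraries at day 5 of differentiation (D5), 3 control libraries at day 7 (D7), and 3 D7 libraries given 500 ng/ml doxycycline for 48 hours to overexpress GLI1. Per the labels' protocols, 150000 cells were collected, and transposition ran for 30 minutes at 37 C.

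The deposited data used here are 3 peak lists, 1 for each group, so each list pools the libraries of its group. The submitters' processing notes name Bowtie2 2.3.2, SAMtools 1.5, Picard, MACS2 2.1.1 and the mouse build mm10. The D7 control list was recognised by its name, which pairs with that of the doxycycline list, and by D5 having a list of its own; its assignment to D7 is therefore an inference. In each list the authors give every peak a fold enrichment over the background, which is a ratio made by the peak caller. The authors also give each peak a −log10 p and a −log10 q, and a score in the deposited lists that holds 10 times the −log10 q. The other deposited column gives the offset of the summit from the peak start, in bases. These are the authors' own values for each peak, and they served to describe, rank or filter peaks. The thresholds for strong regions and for depth used the lowest fold of the other D7 list. Gained and lost regions of like fold, each in its own list, were also compared. Only near Ptch1 and Foxf1 are folds of shared regions set side by side between the D7 lists.

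Every fold in both D7 lists was, to within 0.02 steps, a whole multiple of 1 step and went with 1 p-value, so these lists were called against a constant background. The step and the deposited −log10 p gave the background as 4.56 reads per base in the D7 control list and 4.70 in the GLI1 list, which was 3.11% higher. The D5 list had a local background, and its most common folds gave 0.376 reads per base, 12.1 times below the D7 control list; the extension of reads could also have differed, because the shortest peak was 124 bp at D5 and 200 bp at D7. Peak numbers in the D7 lists had gaps (978 missing in control and 1071 with GLI1), as after the removal of blacklisted peaks, and the D5 numbers had none. Read totals of the libraries were not used here, so depth is known only through these backgrounds. The D5 list differs from the D7 lists in depth and in calling, and this limits each comparison with D5.

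Peaks on chromosomes 1 to 19, X and Y were used, and overlapping peaks of a list were merged into regions with bedtools 2.31.1. A region was counted as shared when it overlapped a region of the other list by at least 1 base. Regions of the GLI1 list without a D7 control region are called gained, and the opposite class lost. Regions of the D7 control list without a D5 region are called opened, and the opposite class closed. Because each group has 1 list, replicates could not be compared, no library could be left out, and no p-value between conditions is given. Shares carry Wilson 95% intervals, which cover counting error only. A gained or lost region was called strong when its fold was at least 2 times the lowest fold of the other D7 list, a threshold chosen after the lists were examined.

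Each region was assigned by its summit to the nearest of 21027 protein-coding genes within 100 kb, using RefSeq gene intervals of the mm10 assembly. The annotation used here gives neither strand nor exons, so gene intervals replaced the planned distances to transcription start sites, and exon or intron status is not stated. A planned search for GLI binding sequences needed the genome sequence and was not run. For 13 gene lists with 280 distinct genes, all matched to the annotation, the percent of gained minus lost regions was placed among 10000 random lists of the same size, matched gene by gene on the decile of the number of regions. A list at or above the 97.5th percentile, or at or below the 2.5th, is said to stand apart; 0.65 of 13 lists would do so by chance. These percentiles describe the lists and are not p-values. The lists hold 302 entries, so they share genes, of which these are examples. Foxf1 and Foxc2 are in both the forkhead and second heart field lists, and Foxa1, Foxa2 and Foxa3 in both the forkhead and endoderm lists. The paraxial mesoderm list shares Pax7 with the neural progenitor list and Foxc1 with the forkhead list. The primitive streak list shares Hand1 with the cardiac transcription factor list and Kdr with the endothelial list.

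The groups, gene lists, main definitions and the rule for named genes were fixed before the data were examined. The rule took Gli1, Ptch1, Hhip and Foxf1 whatever their values, the 10 genes with the largest and the 10 with the smallest gained minus lost count, the 8 and 8 for opened minus closed, the 2 most extreme genes each way in each list where the net count was at least 2 in size, and the 5 gained and 5 lost regions with the highest −log10 q. Some items that the rule took are not reported here. Genes named outside this rule are said to be so. Alternatives were an overlap of at least 50% of the shorter region, a gap of up to 500 bp, a −log10 q of at least 5, equal list lengths of 48177 peaks, peaks without merging, and a gene distance of 25 kb. Regions were compared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

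The steps were tested on simulated data. A second overlap implementation differed for 0 of 242500 regions, and 200 of 200 planted losses and 200 of 200 planted gains were found. For the GLI1 contrast over 15113 genes, 40 of 40 planted lists of 25 genes, with a gain probability of 85%, passed the upper threshold, and 6 of 200 unchanged lists passed either threshold.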

Results

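ATAC-seq peak lists were compared for mouse embryonic stem cell-derived cardiac progenitors at 2 stages and after induction of GLI1, a transcription factor at the end of the Hedgehog signalling pathway. The D5 control list held 48177 peaks from 2 pooled libraries, the D7 control list 59488 peaks from 3, and the D7 GLI1 list 65318 peaks from 3. After merging, these made 39436, 38771 and 43043 accessible regions that covered 13.1, 27.2 and 29.1 Mb. No difference below has a replicate check, since each group is represented by 1 pooled list.

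The comparison of GLI1 with control at D7 addressed which chromatin opened or closed when GLI1 was induced for 48 hours during cardiac differentiation. The induced gene came first: 6 regions within Gli1 itself, at chromosome 10, 127329882 to 127341579 (mm10), were present with GLI1 and absent in control, with folds from 9.30 to 19.3 and widths from 331 to 1819 bp. Of 3 further genes fixed in advance, Foxf1, a forkhead factor of mesenchyme, had 6 gained and 0 lost regions, Hhip, which encodes a Hedgehog-binding inhibitor, had 8 gained and 1 lost, and Ptch1, the Hedgehog receptor, had 8 gained and 3 lost. In the genome as a whole 16766 regions were gained and 12271 lost, while 26277 regions of the GLI1 list were shared with control.

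At Foxf1 (chromosome 8, 121084386 to 121088154) the strongest gained region within 20 kb lay outside the gene at 121072985 to 121074068, with a fold of 31.9 in the GLI1 list. At Hhip (chromosome 8, 79965850 to 80058060) a gained region inside the gene at 80049115 to 80049963 had a fold of 19.1 and overlapped a D5 region. Within 20 kb of Ptch1 (chromosome 13, 63508328 to 63573460) there were 3 gained and 4 lost regions, none of them strong among the gained. The net gain of Ptch1 in number of regions came from farther away. Counted within 25 kb in place of 100 kb, its gained and lost regions were equal in number. These counts leave out changes of fold at shared regions. At the end of Ptch1, a shared region at 63572096 to 63574064 had a fold of 55.8 with GLI1. The control regions it overlapped had folds of at most 5.22. A shared region at Foxf1 (121082596 to 121085223) had 50.4 with GLI1 against 10.8 in control. Not all shared regions rose: near Foxf1, that at 121107782 to 121108695 had 22.8 against 27.9. Whether the gained regions inside Gli1 come from the endogenous gene or from an induced copy was not determined, since exons and reads were not used here.

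The gained regions with the highest −log10 q had other genes as the nearest, though the second and the fifth lay between Ptch1 and Hsd17b3. The first was in Il16, an interleukin gene, at chromosome 7, 83737213 to 83739260, with a fold of 62.5. The second, at chromosome 13, 63979735 to 63981230, had a fold of 59.7 and lay 77.8 kb from Hsd17b3. The third was in Nhej1, a DNA repair gene, at chromosome 1, 75040016 to 75042347, with a fold of 54.4. The fourth, at chromosome 13, 111396847 to 111398497, lay 27.9 kb from Gpbp1 with a fold of 53.0, and the fifth, at chromosome 13, 64002827 to 64004128, lay 55.0 kb from Hsd17b3 with a fold of 41.8; both of these overlapped D5 regions. Lost regions with high −log10 q were in Atp6v1b1 (chromosome 6, 83748720 to 83749997, fold 41.4), in Ntn1, which encodes the guidance cue netrin 1 (chromosome 11, 68320740 to 68322042, fold 33.7), and in Bend6 (chromosome 1, 33897590 to 33899298, fold 30.6). Another was in Maats1 (chromosome 16, 38300639 to 38302081, fold 25.7).

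**Figure D1:**
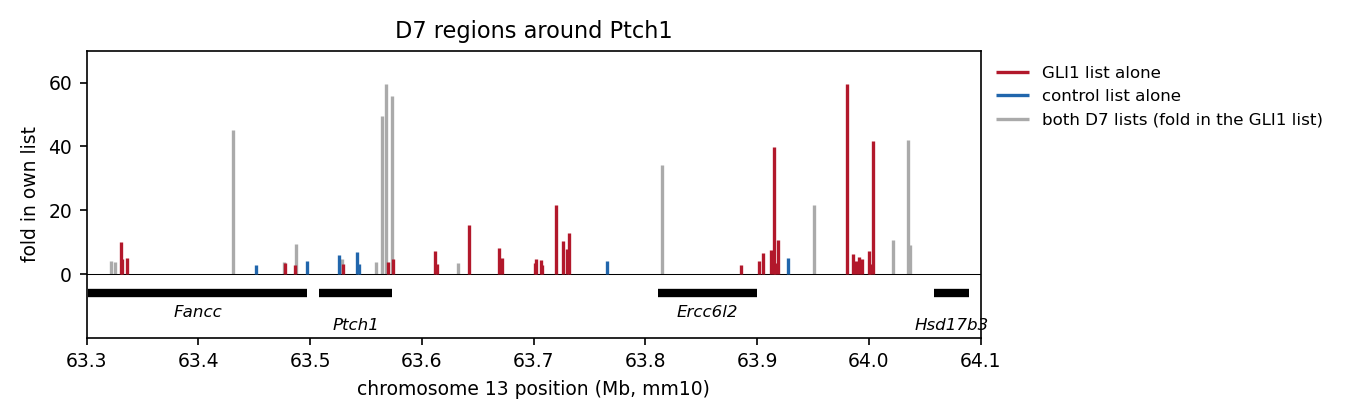
Fold enrichment of D7 regions along chromosome 13 around Ptch1 (position in Mb, mm10; fold in the list each region is from); red lines are regions in the GLI1 list alone, blue lines in the control list alone, grey lines in both, and black bars are genes. Between Ptch1 and Hsd17b3, an interval chosen after the values were seen, there are 29 gained and 2 lost regions, with folds of up to 59.7 among the gained.

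Genes with the most gained over lost regions included Foxa2, a forkhead factor of endoderm and floor plate, with 11 gained and 0 lost, and Foxp1, another forkhead gene, with 19 gained and 5 lost. Ebf1 had 12 gained and 0 lost, Adgrv1 15 and 0, and Dlg2, a synaptic scaffold gene, 19 and 2. Trabd2b had 15 gained and 5 lost, Mpped2 and Magi2 each 12 and 2, and Ercc6l2 and Mtcl1 each 11 and 2. Among genes with more lost than gained regions, Bcar3 had 2 gained and 11 lost, Pard3, a cell polarity gene, 3 and 12, and Hspg2, which encodes the basement membrane proteoglycan perlecan, 1 and 9. Prkce had 7 gained and 14 lost, Disc1 3 and 10, Zfp423 4 and 11, Tmem108 3 and 10, Grm4 5 and 12, Zfp608 1 and 8, and Frem1 0 and 7. Long genes collect more regions, and these counts are not scaled by length: Dlg2 spans 1973 kb and Foxa2 4.09 kb. With regions assigned to the nearest gene end in place of the nearest gene, the net of Dlg2 went from 17 to 1, that of Adgrv1 from 15 to 7, that of Magi2 from 10 to 2, that of Foxp1 from 14 to 7 that of Ebf1 from 12 to 9 and that of Pard3 from −9 to −5. Prkce went from −7 to −3, and Zfp423 and Tmem108 from −7 to −4. The net of Foxa2, Trabd2b, Mpped2, Ercc6l2, Mtcl1, Bcar3, Hspg2, Disc1, Grm4, Zfp608 and Frem1 stayed the same.

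Forkhead transcription factor genes stood apart as a group. Of the 265 D7 regions at 37 forkhead genes, 111 were gained and 46 lost, a net of 24.5% against a 95% range of −3.54% to 18.7% for matched random lists, and 22 of these genes had more gained than lost regions while 7 had fewer. The list lay at the 99.86th percentile, and at the 98.9th when its most influential gene, Foxa2, was left out. Foxc1, with 1 gained and 4 lost, and Foxl1, with 1 and 3, went the other way. Genes of the second heart field, the progenitor pool that adds to the growing heart tube, had 75 gained and 33 lost of 195 regions, at the 98.86th percentile, with Tbx1 at 8 gained and 1 lost and Foxf1 at 6 and 0. With equal list lengths Tbx1 had 2 gained and 1 lost, and among strong regions 0 of either. This place was lost without Tbx1 (96.5th percentile) or without Foxf1 (97.0th), and without both forkhead members of the list it was the 96.7th. Endoderm genes had 40 gained and 13 lost of 83 regions, at the 99.5th percentile, with Foxa2 at 11 and 0 and Prox1 at 10 and 4. This call ended without Foxa2 (92.1st percentile), at a −log10 q of at least 5 (94.7th) and with equal list lengths (86.9th). Prox1 had 5 gained and 4 lost at that −log10 q, 4 and 4 with equal list lengths, and 0 and 2 among strong regions.

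The other 10 lists lay within the range of random lists. In every list a region in both D7 lists counted as unchanged whatever its folds, so a rise in fold alone, as at Ptch1 above, is not seen here. Hedgehog pathway genes had 53 gained and 29 lost of 152 regions (89.0th percentile), with Gas1, a Hedgehog co-receptor, at 0 gained and 5 lost. Cardiac transcription factor genes had 39 gained and 38 lost (16.4th percentile): Mef2c had 4 gained and 0 lost and Hey1 3 and 0, whereas Prdm16 had 4 gained and 10 lost and Hand1 0 and 3. Contractile and calcium handling genes of cardiomyocytes had 35 gained and 39 lost (6.73rd percentile), and 13 of these genes had more lost than gained regions against 6 with more gained; Myl7, an atrial myosin light chain gene, had 0 gained and 3 lost, Slc8a1 3 and 5, Tpm1 6 and 2, and Tnni1 4 and 1. The net of Tpm1 changed sign, to −1, with equal list lengths. Housekeeping genes had 8 gained and 12 lost (5.23rd percentile), with Eef1a1 and Hprt each at 0 and 2.

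Endothelial and blood genes had 44 gained and 24 lost regions (88.0th percentile), with Erg at 9 and 1, Cdh5, which encodes VE-cadherin, at 6 and 2, and Fli1 at 0 and 3. Neural progenitor genes had 44 gained and 40 lost (22.7th), with Zic1 at 6 and 0, Nkx2-2 at 6 and 1 and Irx3 at 0 and 5. Primitive streak and early mesoderm genes had 27 gained and 17 lost (69.985th), with Gsc at 5 and 1 and Kdr at 1 and 3, and pluripotency genes 21 and 14 (59.0th), with Tfcp2l1 at 3 and 0 and Klf4 at 0 and 2. Smooth muscle, epicardial and fibroblast genes had 28 and 20 (57.9th), with Pdgfrb at 4 and 0 and Prrx1 at 1 and 5. The net of Pdgfrb changed sign, to −1, at a −log10 q of at least 5 and with equal list lengths. Paraxial mesoderm and skeletal muscle genes had 28 and 26 (24.955th), with Ripply2 and Nkx3-2 each at 4 and 0 and Sox9 at 1 and 4. Within 25 kb Sox9 changed sign, to a net of 1.

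**Figure D2:**
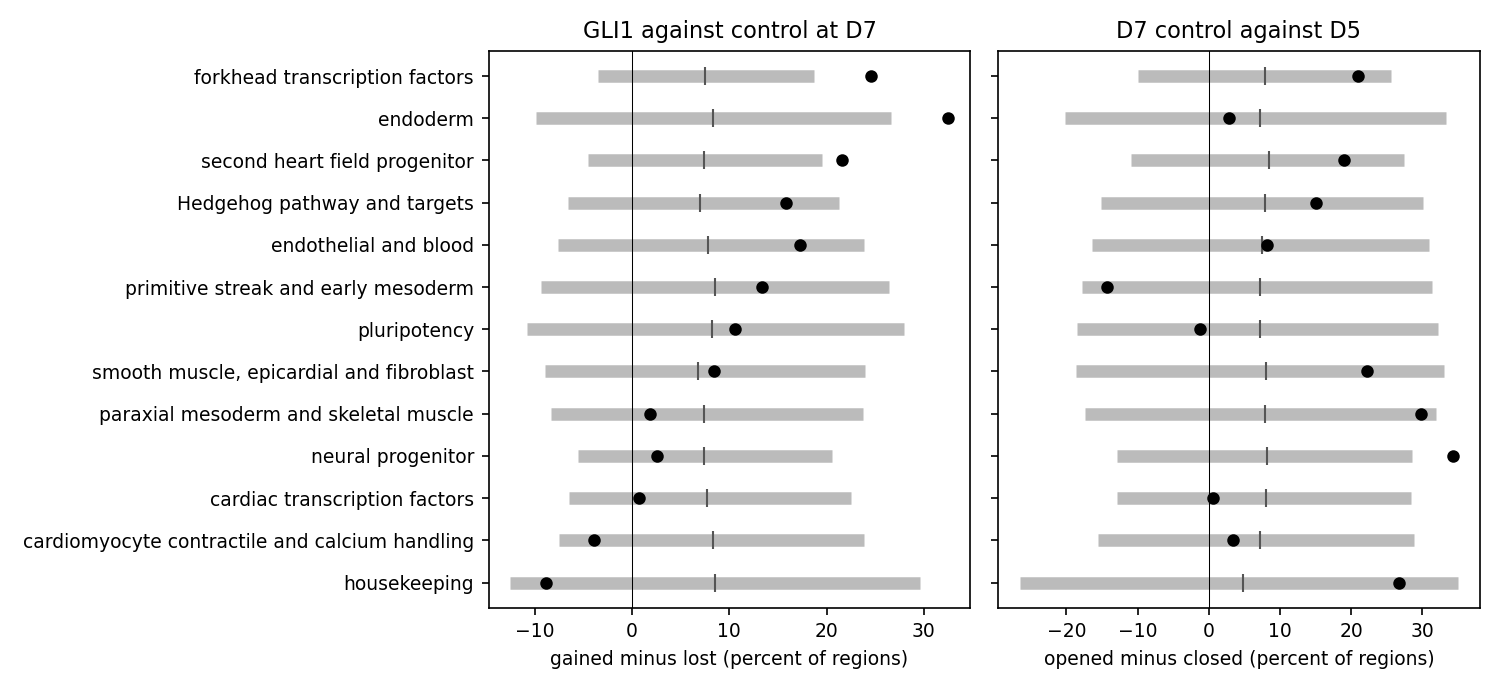
Net change of accessible regions at the genes of 13 lists (rows), as gained minus lost for GLI1 against control at D7 (left) and opened minus closed for D7 control against D5 (right), in percent of the regions of the list; points are the lists, grey bars the 95% range and ticks the median of 10000 matched random lists. Forkhead, endoderm and second heart field genes lie above the range on the left (endoderm genes not with equal list lengths, at the 86.9th percentile), and neural progenitor genes on the right.

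Most gained and lost regions were weak. The median fold was 3.86 for gained, 3.96 for lost and 9.83 for shared regions of the GLI1 list, and 76.8% of gained and 75.5% of lost regions were below the threshold for a strong region. There were 3897 strong gained and 3004 strong lost regions. The classes parted most at high folds, where 642 gained and 333 lost regions reached a fold of 10 in their own list (4.66% and 2.45% of all its regions at that fold), and 98 gained and 13 lost regions reached 20. Gained and lost regions lay mainly away from gene ends: 9.52% of gained (9.08 to 9.97) and 7.16% of lost regions (6.71 to 7.62) had their summit within 1 kb of a gene end, against 43.8% of shared regions (43.2 to 44.4). With equal list lengths, 9256 regions were gained and 9032 lost, which are nearly equal by construction. Doxycycline was given to the GLI1 group alone, so its own effect is not separated from that of GLI1.

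The comparison of D7 with D5 control cells addressed how chromatin changed with time without induction of GLI1 by doxycycline. Genes of neural progenitors opened regions to a greater extent than matched genes, with 78 opened and 29 closed of 143 regions (99.4th percentile). Irx3 and Pax7, both developmental transcription factor genes, had 9 opened and 2 closed regions each. Pax7 is also in the paraxial mesoderm list, and the neural list was not examined with single genes left out. The genes with the most opened over closed regions were Gse1 (46 and 3), Tns1, a focal adhesion gene (21 and 2), Ebf2 (19 and 1), Septin9 (19 and 2), Disc1 (17 and 0), Zfp423 (18 and 2), Grm4 (16 and 0) and Col13a1 (16 and 1). Among the genes with the most closed over opened regions were long genes, namely Dlg2 (2 opened and 26 closed), Macrod2 (12 and 35), Syt1 (1 and 18), Agbl4 (0 and 17), Cntn5 (3 and 18), Tenm2 (10 and 25) and Csmd1 (4 and 19), each of at least 513 kb. With regions assigned to the nearest gene end, the net of Dlg2 went from −24 to 0, that of Macrod2 from −23 to −2 and that of Csmd1 from −15 to −2. Agbl4, Cntn5 and Tenm2 each went to −7, whereas Syt1 stayed at −16 against −17. Of the opened genes, Gse1 went from 43 to 12, Tns1 from 19 to 7 and Zfp423 from 16 to 8, and the other 5 did not change. At a −log10 q of at least 5, the closed genes had smaller nets. Syt1 and Agbl4 were each at −5, Macrod2 and Csmd1 each at −8, Cntn5 at −10 and Dlg2 at −11. Tenm2 was at 0, with 6 opened and 6 closed regions. The opened genes had nets from 12 (Grm4) to 32 (Gse1) at that cutoff.

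Primitive streak and early mesoderm genes had 25 opened and 37 closed regions (4.49th percentile), with Gsc at 1 and 5 and Evx1 at 0 and 4. Paraxial mesoderm and skeletal muscle genes had 63 and 29 (96.2nd), with Meox1 at 7 and 0 and Pax1 at 2 and 6. Forkhead genes had 108 and 61 (92.8th), with Foxp1 at 14 and 8 and Foxa2 at 0 and 7, and housekeeping genes 19 and 7 (92.1st). Smooth muscle, epicardial and fibroblast genes had 43 and 23 (86.3rd), with Pdgfrb at 7 and 0 and Tcf21 at 7 and 1, and second heart field genes 76 and 44 (85.9th), with Bmp7 at 13 and 1 and Fgf10 at 1 and 4. Hedgehog pathway genes had 58 and 37 (72.9th), with Gas1 at 9 and 1 and Gli3 at 3 and 12. Endothelial and blood genes had 47 and 38 (52.5th), with Fli1 at 11 and 0 and Flt1 at 4 and 9. Endoderm genes had 29 and 27 (38.5th), contractile genes 50 and 46 (37.1st), with Myl4 at 5 and 0 and Ryr2 at 3 and 8, pluripotency genes 30 and 31 (26.6th), with Sox2 at 7 and 1 and Zfp42 at 1 and 4, and cardiac transcription factor genes 59 and 58 (24.1st), with Prdm16 at 15 and 1 and Tbx20 at 1 and 5.

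In all, 21310 regions were opened by D7, or 55.0% of the D7 control list, and 19719 were closed, or 50.0025% of the D5 list. Closed regions lay more than 100 kb from a gene in 20.8% of cases (20.3 to 21.4), and opened regions in 12.8% (12.3 to 13.2). At a −log10 q of at least 5 only 8532 regions were closed, and the D5 list had a background 12.1 times lower, was called against a local background and kept blacklisted positions as far as its peak numbers tell. Opened and closed counts therefore mix change with time and differences between the lists.

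The last comparison asked whether regions that set GLI1 apart from control at D7 were ones already accessible at D5. Gained regions were in the D5 list more often than lost regions: 13.5% of gained (2258 of 16766; 12.96 to 13.99) against 8.95% of lost (1098 of 12271; 8.46 to 9.47). The gained regions in Hhip and near Gpbp1 described above were among those present at D5.

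The difference held at each level of strength, though in the lowest bin it was small. Below a fold of 4, 9.26% of gained and 7.87% of lost regions were in the D5 list; between 5 and 7 these were 21.2% (19.6 to 22.9) and 10.9% (9.56 to 12.4), and at 15 and over 17.6% (13.2 to 23.1) and 3.45% (0.951 to 11.7, from 58 lost regions). Intervals overlapped between 10 and 15, at 10.6% (7.99 to 13.9) and 6.55% (4.18 to 10.1). Of shared regions, which were stronger, 62.1% were in the D5 list; below a fold of 4 it was 18.8%. Random regions of the same list with like −log10 q were in the D5 list in 21.4% of cases for gained and 22.3% for lost regions (medians of 1000 sets). Of the regions closed between D5 and D7 control, 12.5% (2472 of 19719; 12.08 to 13.01) were present with GLI1. The opposite case, D5 regions absent with GLI1 and present in control, made up 6.42% (1184 of 18431; 6.08 to 6.79). If the D5 regions found in 1 D7 list had been divided as all gained and lost regions were, 10.9% of closed regions would have been present with GLI1.

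**Figure D3:**
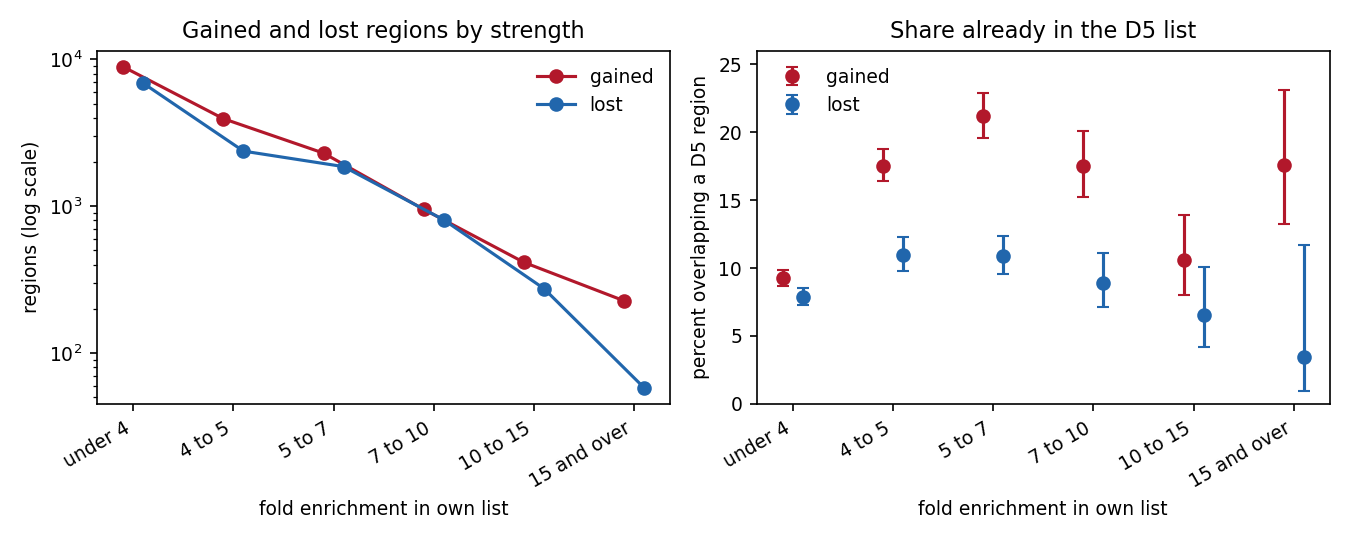
Number of gained (red) and lost (blue) regions on a log axis (left) and percent of them that overlap a D5 region (right), by fold enrichment in their own list; bars are Wilson 95% intervals, which cover counting error only. At a fold of 15 and over there are 227 gained and 58 lost regions, and between 5 and 7 the D5 share is 21.2% for gained and 10.9% for lost regions.

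Of the regions opened between D5 and D7, 52.4% (51.8 to 53.1) were absent with GLI1. If the regions found in 1 D7 list and absent at D5 had been divided as all gained and lost regions were, this share would have been 51.7%. It is the other side of the same comparison and no separate result, since 91.1% of lost and 86.5% of gained regions were absent at D5. Of the regions of the GLI1 list absent at D5, 59.3% (58.7 to 59.9) were absent in control, a share that carries the greater number of gained regions. The low depth and other calling of the D5 list limit all of these shares.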

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

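The strong-region threshold, assignment to the nearest gene end, and lists without Gli1 or without forkhead genes were chosen after seeing the data. No paired analysis was possible because each group has 1 pooled peak list, although the labels number the replicates; for the same reason no library could be left out. The GLI binding sequence and its alternatives were not run. Gained regions exceeded lost ones under all 6 alternatives, by 1.02 to 1.39 times (1.02 with equal list lengths, nearly equal by construction), and the share in the D5 list was higher for gained than for lost regions by 3.78 to 9.14 percentage points. The forkhead list stayed between the 99.04th and 99.95th percentile under 5 alternatives, and neural progenitor genes for D7 against D5 between 98.6 and 99.3 under 4. Gene lists and net counts of genes were not run with the overlap of 50%, the gap of 500 bp or peaks without merging. With a gap of up to 500 bp, the alternative that could place them in both lists, all 10 regions taken by the naming rule remained in 1 D7 list alone. The cause of the changes below was not tested, except that stricter or shorter lists hold fewer regions. With an overlap of at least 50% of the shorter region, 12.6% of gained and 8.16% of lost regions were in D5 and 55.2% of opened regions were absent with GLI1. With a gap of up to 500 bp these were 16.7%, 11.5% and 48.1%, and 13.1% of closed regions were present with GLI1. At a −log10 q of at least 5 there were 8532 closed regions, and the percents were 9.44, 5.66, 45.6 and 13.1. With equal list lengths 9256 regions were gained, and the percents were 20.2, 12.7, 54.7 and 10.1. For peaks without merging, 47.9% of opened peaks were absent with GLI1. Among strong regions alone, 3897 were gained and 3004 lost, and 18.96% and 9.82% were in D5. For D7 against D5, 2 lists stood apart at 25 kb (primitive streak genes entered, at the 1.41st percentile) and 3 at a −log10 q of at least 5 (paraxial mesoderm at 98.9 and smooth muscle at 98.3 entered). The endoderm list fell to the 94.7th percentile at a −log10 q of at least 5, 86.9 with equal list lengths, 73.4 among strong regions and 86.9 without forkhead genes; the second heart field list fell to 93.0 among strong regions and 96.7 without forkhead genes. The Hedgehog list reached 97.6 among strong regions. Among regions of any strength it was at 89.0 with Gli1 and 76.8 without it, and strong regions were not run without Gli1. Of the net counts of genes taken by the rule, 6 of 300 values for GLI1 and 5 of 256 for time changed sign, and 135 and 76 changed by more than 1.5 times. With the nearest gene end, Dlg2 fell to a net of 1 (0 for time) and Gse1 to 12 for time, while the same 3 lists for GLI1 and 1 for time stood apart. Changes of sign were Sox9 (1), and for time Apob (1), Kdr (−2) and Tbx3 (2), at 25 kb; Pdgfrb (−1), and for time Zfpm2 (1) and Wt1 (1), at a −log10 q of at least 5; Tpm1 (−1), Pdgfrb (−1) and Tbx18 (−1) with equal list lengths; and Prox1 (−2) among strong regions.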

Other observations

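The tests in this part were chosen after the results were seen, except the raised cutoff for depth. Genes that this part names beyond those of the report were chosen after their values were seen. Between Ptch1 and Hsd17b3 on chromosome 13 (63573461 to 64058273, 485 kb), 29 regions were gained and 2 lost, and 8 gained regions but 0 lost ones reached a fold of 10. They include regions with folds of 59.7 and 41.8, which were among the 5 gained regions with the highest −log10 q, and 1 near Ercc6l2 with a fold of 39.7. The 1 Mb window that holds Ptch1 had 8 gained regions at that fold, the most of any, followed by windows with 5 each at Gli1 (chromosome 10), at Pdzrn3 (chromosome 6), at 121 to 122 Mb of chromosome 8 (4 of the 5 nearest 1700018B08Rik and 1 nearest Foxf1) and at Thsd4 and Larp6 (chromosome 9). Windows with 4 were the one before it on chromosome 8, 1 at Trabd2b and Foxd2 on chromosome 4, and 1 at Col13a1, Macroh2a2 and Pald1 on chromosome 10. In all, 8 windows held 4 or more gained regions at that fold. None of 1000 random draws of 642 regions from all gained regions gave as many, but 114 of 1000 draws from all regions of the GLI1 list at that fold did. Gathering beyond that of high-fold regions in general is therefore not shown. The most for lost regions was 4, in a window on chromosome 8 (3 nearest Zfp703 and 1 nearest Thap1).

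These windows led to the hypothesis that gained regions with a fold of at least 10 lie near Hedgehog pathway genes over longer distances. Within 500 kb of 19 Hedgehog genes, Gli1 left out, 20 regions with a fold of at least 10 were gained, or 4.34% of the gained and shared regions counted, at the 99.955th percentile of 10000 matched random lists. The same count for lost regions was 6, at the 92.8th percentile. The Ptch1 window that prompted this count is part of it, so that percentile repeats what was seen. Ptch1 had 9 of the 20. Without it the list was at the 94.7th percentile of random lists of all genes, and at the 98.2nd when genes near the 8 windows were left out of the random lists too. Whether Hedgehog genes other than Ptch1 stand apart is therefore not decided. Ihh, Gli3 and Spop had 2 gained each (Spop also 1 lost), and Gas1 (0 gained and 2 lost), Cdon (1 and 2) and Sufu (0 and 1) had more lost.

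Forkhead genes had 29 such gained regions near 16 genes, against 4 lost ones. Counted gene by gene there were 49, mainly because Foxf1, Foxc2 and Foxl1 share 8 of them. Without these 3 and Foxd2, the forkhead genes near the 8 windows, a count of 21 was left, at the 99.005th percentile of random lists of all genes and the 99.9th without genes near the windows. Second heart field genes fell to the 94.97th and 96.6th without Foxf1 and Foxc2, both short of the threshold. Paraxial mesoderm genes without Foxc2 were at the 97.1st and 99.6th, so their place depended on the random lists.

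Among 64 groups of genes whose symbols share their first letters, with at least 100 regions each, the groups Olf (69 gained and 31 lost) and Fox (113 and 46) had the highest net percent, 28.4 and 24.2. They were the 2 groups above the upper percentile threshold, and 1 group, Ppp, with 45 gained and 54 lost, was below the lower one, against 1.6 expected on each side by chance. Numbered olfactory receptor genes, which do not make up the whole group Olf, had 63 gained and 27 lost regions. The regions gained at these receptor genes were about as weak as gained regions in general, with 79.4% against 76.8% below the threshold for a strong region.

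The GLI1 list had more regions of its own than the control list. A greater depth by the 3.11% seen in the backgrounds is argued against: with the GLI1 peaks kept only above the lowest control fold raised by that ratio, gained regions still outnumbered lost ones 1.32 times. That cut dropped 718 of 65318 GLI1 peaks, so it could lower the excess of gained regions only a little and speaks only to a gap of that size. At a fold of at least 20 the ratio was 7.54 (98 and 13), far above what a small difference in depth could give. Equal list lengths bring the ratio to 1.02, but that step makes both classes nearly equal by construction and decides nothing. Differences in enrichment between the pooled libraries and an effect of GLI1 or doxycycline stay open for regions of any strength.

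The source of the regions gained inside Gli1 was not settled. Of the strong gained regions there, 6 lay inside the gene and 0 within 20 kb outside. Reads from the induced Gli1 coding sequence and opening of the endogenous gene would both give this, and it is the observation that led to the test, so it supports neither. Opening of the whole surrounding domain is not excluded, since 3 weak gained regions lay outside Gli1, with folds from 3.51 to 4.56. Exons and reads were not used here.

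The larger D5 share of gained regions held among regions of like fold and among those in or near genes of at most 300 kb. When the regions found in 1 D7 list were exchanged between the lists within deciles of fold, the highest of 1000 differences was 1.203 percentage points, against 4.52 observed. D5 regions moved along the chromosomes by 50 kb steps overlapped at most 1.49% of gained and 1.61% of lost regions. Placement at random would therefore give only a small part of either share. Because D5 regions cover little of the genome, this low overlap was nearly fixed beforehand. It does not test why gained regions exceed lost ones. Among regions in or near genes of at most 300 kb the difference was 4.66 points, which argues against D5 peaks in gene-poor sequence as the source. Matching on fold in the own list does not remove a difference in enrichment between the pooled libraries, so this stays open. An effect of GLI1 or doxycycline and a difference between the pooled cultures in stage or cell composition stay open too. None of these was tested.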
